A study of Mus musculus with 2 samples.

How the data were processed

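MicroRNA sequencing was available for 2 samples of 1 group, limb tissue of mouse embryos at embryonic day 14.5. Per the labels, the samples were biological replicates collected on different days, with inserts under 30 nucleotides. The labels described each sample as 4 limbs of 1 pup and also gave the sex as pooled, so whether a sample came from 1 embryo or several is open. Both samples carried the same donor and pup labels, and that they came from different animals rests on the replicate numbers and collection days alone. The SDs and the coefficient of variation are limited in the same way. P-values between the libraries compare these 2 samples alone. The binomial test sets their reads against counting noise, and the permutation tests shuffle genes or loci, so none measures the spread between samples. Part of the difference between the libraries may be technical.

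The deposited values were raw counts of reads per gene, whole numbers with no normalization. Per the read-me texts deposited with the tables, reads had been aligned to the mm10 mouse genome and counted on GENCODE annotation M4. The aligner, the counting program and their settings were not given in the sources used here. Each table had 3 count columns without a header and 4 tally rows for reads not given to a gene. The columns were taken as counts on either strand, on the gene's own strand and on the opposite strand, judged from the values, since the second column kept nearly all of the first. Within a library the 3 columns summed, with their tally rows, to 1 total of reads. Own-strand counts were used for the main results.

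Unmapped reads made up 13.2% ± 0.628 of all reads (SD, n = 2), reads with several alignments 32.2% ± 0.558 and reads that lay on the own strand of no annotated gene, opposite-strand reads included, 4.25% ± 0.0792. These tally rows were kept out of library sizes and tests. Own-strand counts made up 50.3% ± 1.26 of all reads. Reads with several alignments were not given to genes, so microRNAs with identical copies were undercounted. No molecular identifiers were recorded in the tables, so intervals and floors cover counting error only. The floor of 3 counts equals 0.651 CPM in replicate 1 (4608816 counts) and 0.724 CPM in replicate 2 (4144385 counts).

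Gene names, positions and host genes were taken from GENCODE M21, an annotation of the same build, by gene identifier. Of 1973 genes in the tables, 1894 matched (1815 with the same version), and the 79 unmatched genes held 1.14e-05% of the counts. A gene was called exonic if it overlapped an exon of any other annotated transcript on its strand, intronic if it lay only in introns, and intergenic otherwise. Precursor sequences of M21 were searched for stretches of 22 nucleotides shared between microRNA genes, and 871 genes had at least 1.

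Counts were scaled to CPM by the sum of own-strand microRNA counts. Detection required at least 10 counts in both libraries. The correlation was computed on log2(CPM + 1) over genes with at least 10 counts in total, with a bootstrap interval from 2000 draws of genes (0.9965 to 0.9978 at 95%). The biological coefficient of variation was the common dispersion of edgeR 4.0.16 in R 4.3.3 with TMM factors and an intercept only. Library differences were tested per gene by a two-sided exact binomial test given the library totals, with Benjamini-Hochberg adjustment, at an adjusted p under 0.05 and at least a 2-fold change. Log2 ratios carried a prior count of 0.5. A quasi-likelihood test was not run because 1 library on each side leaves no residual degrees of freedom. The median log2 ratio of each list was ranked among 10000 random lists with as many genes in each of 10 expression bins. A first drawing scheme left too many unshifted simulated lists outside its range and was replaced, and the same 5 lists lay outside under both schemes. Clusters were genes on a strand with gaps of at most 10 kb, and the intraclass correlation of their log2 ratios was tested by 100000 permutations of genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and DESeq2 1.42.0 (size factors) were also used.

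Named genes followed a rule set before the data were examined: the 20 genes with the highest mean CPM, the 3 highest members of each of 16 lists, and up to 5 genes each way among those past the 2-fold threshold with a mean of at least 100 CPM. No gene met the last part. Other genes named in the text were chosen after their values were seen. The lists, most tests and most alternatives were fixed before the data were examined. For clusters the plan named a range and a correlation but no test. The permutation test of the intraclass correlation was thus not part of the plan. Alternatives chosen after seeing the data were the total with reads of several alignments, the sum of own-strand and opposite-strand reads, the removal of a GC trend, genes without a shared stretch and clusters without the largest of the Dlk1-Dio3 locus.

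The scripts were tested on simulated data. Of 97 genes simulated with a 3-fold difference between the replicates, 91.8% were called among 406 genes. Of those with a 1.5-fold difference 4 of 97 were called, and of unchanged genes 0 of 212. Simulated counts held Poisson noise only, the counting noise that the binomial test assumes. They do not show how often the test calls unchanged genes in samples that vary by more. Simulated coefficients of variation of 5%, 10% and 30% were estimated at 4.42%, 9.61% and 31.5% over 406, 406 and 411 genes. Of 500 unshifted lists of 45 genes among 407, 6% lay outside the middle 95% of random lists. Their genes had independent simulated values, so this rate does not cover lists of neighbouring genes that share their deviations. Simulated intraclass correlations of 0.5 averaged 0.505. The opposite-strand column was kept out of the main values. It entered the alternatives that add its reads to a list and the map of the Dlk1-Dio3 locus, and it is described among the additional observations.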

Results

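The data were small RNA sequencing profiles of whole limb tissue from mouse embryos of the B6NCrl strain at embryonic day 14.5, an age at which cartilage templates, muscle masses and skin are forming. The assay read RNAs under 30 nucleotides, the size class that holds mature microRNAs, which repress target mRNAs. There was 1 group of 2 samples, which the labels called biological replicates 1 and 2, each taken from 4 limbs, with the same donor label on both. The design therefore held no contrast between conditions, and the question was which microRNAs the limb expressed, at what level, and how far the 2 libraries differed. Replicate 1 held 9001596 reads and replicate 2 held 8387546 reads, of which 4608816 and 4144385 were counted on the own strand of an annotated microRNA gene. Levels are given in CPM, the counts of a gene scaled to the library sum of these microRNA counts, as mean ± SD with n = 2. How evenly different microRNAs yielded reads was not measured. Ranks and ratios between genes or lists therefore compare reads, not amounts of RNA in the tissue. Genes at 0 counts were below 0.651 CPM in replicate 1 and 0.724 CPM in replicate 2, the level of 3 counts, a limit that covers counting error only.

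Of 1973 microRNA genes in the tables, 333 had at least 10 counts in both libraries, and 1286 had no count in either. Among the 333 detected genes, 143 lay in an intron of an annotated host transcript and carried 41.8% of the counts. A further 88 overlapped an exon of a host transcript (31.7% of counts) and 102 were intergenic (26.5%). Genes with a mean level of at least 1000 CPM numbered 98, and 23 genes reached at least 10000 CPM.

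Among reads with a single alignment on a gene's own strand, the most abundant microRNA gene of the limb was Mir335, which lies in an intron of the imprinted gene Mest, with 76729 ± 4126 CPM (SD, n = 2) or 7.67% ± 0.413 of all microRNA counts. It was followed by Mir140, the cartilage microRNA inside Wwp2, at 57289 ± 2418 CPM, and by Mir322, an X-linked gene of the miR-15/16 seed family, at 53715 ± 1675 CPM. Mir196b, which lies at Hoxa9 in the HoxA cluster and represses Hox mRNAs, reached 51975 ± 3475 CPM. Mir99a and Mir23b followed at 50157 ± 294 CPM and 44668 ± 2530 CPM. The 10 most abundant genes, which also included Mirlet7g, Mir203, Mir214 and Mirlet7i, took 47.2% ± 0.163 of the counts. The 50 most abundant genes took 85.5% ± 0.0111 and the 100 most abundant 96.2% ± 0.00268. In GRCm38 coordinates, Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 from 30741299 to 30741396, Mir140 (ENSMUSG00000065439.1) on chromosome 8 from 107551244 to 107551313, and Mir196b (ENSMUSG00000065443.1) on chromosome 6 from 52230081 to 52230165. Ranks 11 to 20 were held by Mir26b (28664 ± 500.5 CPM), Mir130a (27796 ± 1066 CPM), Mir30e (21558 ± 491 CPM), Mir23a (20383 ± 522 CPM), Mir126a, Mir17, Mir99b (16252 ± 1314 CPM), Mir205, Mir127 and Mir411. Shares depend on the total used, and ranks hold among singly aligned reads only, because reads with several alignments made up 32.2% ± 0.558 of all reads and were not given to any gene. With these reads in the total, the share of Mir335 was 4.68% and that of the 10 most abundant genes 28.8%.

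**Figure D1:**
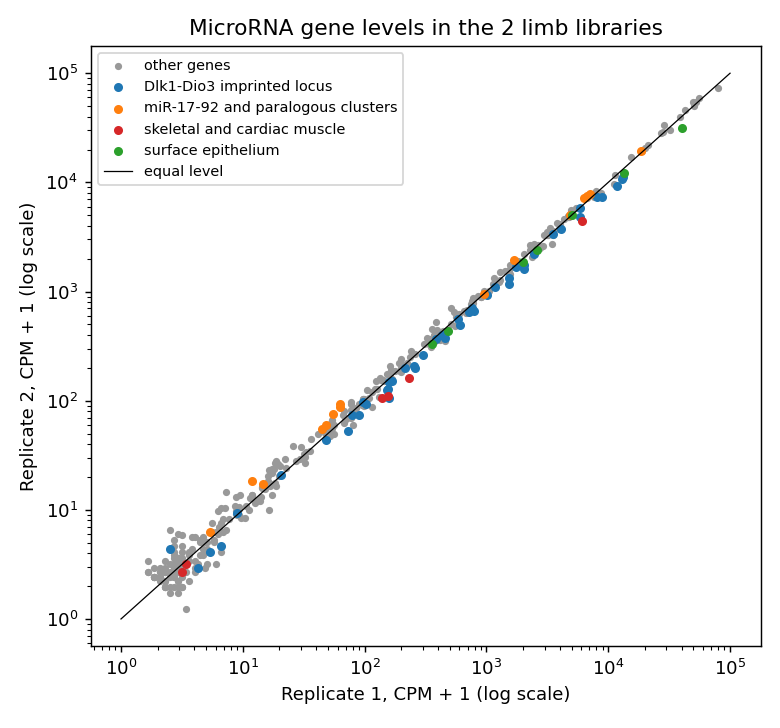
Level of each of 407 microRNA genes with at least 10 counts in total, as CPM plus 1 on log axes, in replicate 1 (horizontal) and replicate 2 (vertical); each point is a gene, colours mark 4 of the fixed lists, and the line marks equal levels. The points follow the line over the whole range (Pearson r = 0.997 across genes), with the muscle and Dlk1-Dio3 genes mostly below it and the miR-17-92 genes on its upper side.

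The microRNAs of the limb were then described by 16 lists of tissue-restricted, developmental or imprinted microRNAs, fixed before the data were examined. The lists of cartilage and of surface epithelium both summed to a high level. How much of each tissue the samples held was not measured. The cartilage list summed to 61361 ± 2547 CPM (SD, n = 2), of which Mir140 gave 93.4%, and its other member Mir455, in an intron of the collagen gene Col27a1, reached 4072 ± 129 CPM. All 7 members of the surface epithelium list were detected, together 59168 ± 7406 CPM. They were led by Mir203, a microRNA of differentiating epidermis, at 35988 ± 6258 CPM, Mir205, a microRNA of basal epithelium, at 12888 ± 848 CPM, and Mir429 at 5062 ± 35.4 CPM. The ratio of the cartilage list to the epithelium list was 0.925 in replicate 1 and 1.17 in replicate 2, so their order was not resolved by the 2 libraries.

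Patterning and mesenchymal microRNAs also ranked high. All 6 members of the list hosted by the Hox clusters were detected and summed to 66798 ± 1957 CPM. Mir196b gave 77.8% of that sum, followed by Mir10b at Hoxd3 and Hoxd4 (10455 ± 978 CPM) and Mir10a of the HoxB cluster (3062 ± 514 CPM). The mesenchyme and smooth muscle list summed to 41175 ± 2498 CPM, led by Mir214 at the noncoding gene Dnm3os (31163 ± 3130 CPM), Mir143 (8368 ± 612 CPM) and Mir199b (1033 ± 18.9 CPM). Mir199b shares sequence with Mir199a-1 and Mir199a-2, so that its count is a lower limit. The ratio of the Hox list to the cartilage list was 1.09 ± 0.0133, and it lay above 1 in both libraries.

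Regulators of growth and differentiation were represented by let-7, which restrains proliferation in differentiating tissues, and by the miR-17-92 family, which promotes proliferation. All 10 let-7 genes in the tables were detected, together 86154 ± 623 CPM, led by Mirlet7g (39181 ± 376 CPM), Mirlet7i (31038 ± 1291 CPM) and Mirlet7d (7527 ± 279 CPM). All 15 genes of the miR-17-92 and paralogous clusters were detected, together 48213 ± 2634 CPM, led by Mir17 (18952 ± 714 CPM), Mir20a (7425 ± 461 CPM) and Mir93 in Mcm7 (7076 ± 528 CPM). The let-7 list was 1.79 ± 0.111 times the miR-17-92 list, above 1 in both libraries, or 1.89 ± 0.109 times with the opposite-strand reads at Mirlet7e and Mirlet7f-1 added. The counts behind both sums are lower limits. Of the let-7 genes 5 of 10, and of the miR-17-92 genes 4 of 15, share a stretch with another gene. The CPM could move either way, since the left-out reads are missing from the total too. With all reads of several alignments added to the total only, let-7 summed to 52514 CPM and miR-17-92 to 29372 CPM. The pluripotency clusters summed to 43.2 ± 6.45 CPM, with 4 of 12 members detected, of which Mir302a (14.5 ± 2.79 CPM), Mir302d (12.2 ± 4.58 CPM) and Mir302b (8.25 ± 0.619 CPM) were highest.

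Imprinted loci also ranked high. The Dlk1-Dio3 locus of chromosome 12, whose microRNAs are transcribed from the maternal chromosome, summed to 88393 ± 9421 CPM over 45 detected of 52 listed genes. Its order against the let-7 list was not resolved, with 95055 against 86595 CPM in replicate 1 and 81731 against 85713 CPM in replicate 2. Its counts were spread over many members: Mir127, which lies antisense to the retrotransposon-derived gene Rtl1, gave 13.7% of the sum at 12133 ± 1471 CPM, followed by Mir411 (11798 ± 1520 CPM) and Mir487b (10496 ± 1758 CPM). The list of the other imprinted hosts summed to 80082 ± 4051 CPM, of which Mir335 gave 95.8%. Mir483 in the growth factor gene Igf2 reached 3228 ± 74.5 CPM, and Mir675 in H19 reached 125 ± 1.15 CPM. The microRNA family repeated in an intron of Sfmbt2 summed to 4365 ± 145 CPM with 10 of 69 members detected, led by Mir467e (1491 ± 86.3 CPM), Mir467d (1158 ± 24.2 CPM) and Mir467c (755 ± 12.7 CPM). Of these 69 genes, 67 share a stretch of 22 nucleotides with another microRNA gene, so their levels are uncertain.

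**Figure D2:**
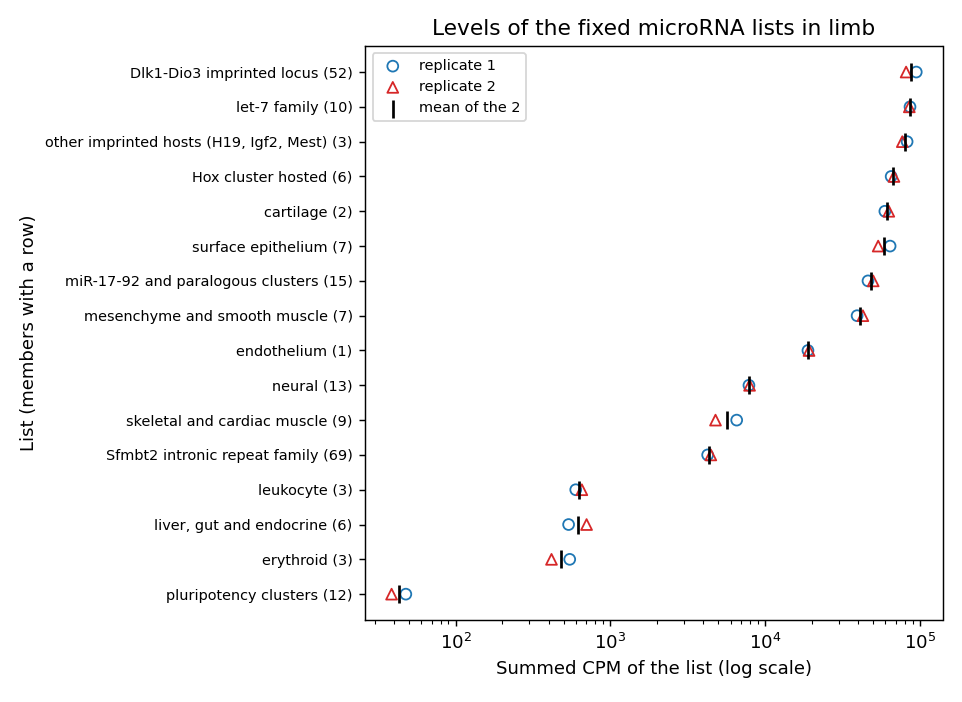
Summed CPM of each of the 16 fixed lists on a log axis, with replicate 1 as circles, replicate 2 as triangles and their mean as a bar; the number of members with a row is in parentheses. The lists span from 43.2 CPM for the pluripotency clusters to 88393 CPM for the Dlk1-Dio3 locus.

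Among singly aligned reads, the lists of blood vessels, muscle, blood and nerve lay below those of cartilage and surface epithelium in both libraries. Mir126a in Egfl7, a microRNA of endothelium and the only listed endothelial gene in the tables, was at 19115 ± 215 CPM. The muscle list summed to 5679 ± 1256 CPM with 4 of 9 members detected. Mir206, a microRNA of skeletal muscle, gave 92.0% of that sum at 5226 ± 1152 CPM, Mir499 in the myosin gene Myh7b reached 195 ± 47.9 CPM and Mir133b 132 ± 32.7 CPM. Mir1a-1, Mir133a-1 and Mir133a-2, which have near-identical copies, held 1 or 2 counts in each library, so the counts behind the muscle sum are a lower limit. The cartilage list was 11.1 ± 2.91 times this sum, above 1 in both libraries, a ratio that holds for singly aligned reads only.

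The erythroid list summed to 482 ± 91.9 CPM, with Mir451a at 405 ± 77.4 CPM, Mir144 at 69.6 ± 14.5 CPM and Mir486, which shares sequence with another gene, at 8.03 and 7.96 CPM in replicates 1 and 2. The leukocyte list summed to 627 ± 40.3 CPM, with Mir223 at 354 ± 11.1 CPM, Mir155 at 262 ± 29.8 CPM and Mir150 at 11.1 ± 0.624 CPM. The blood cell microRNA Mir142 was not among the genes counted on their own strand here and is left out of the leukocyte sum. The endothelial level was 30.5 ± 1.62 times the leukocyte sum, or 15.0 ± 0.531 times it with the opposite-strand reads at Mir142 added, and 40.4 ± 8.15 times the erythroid sum, above 1 in both libraries each. The neural list summed to 7916 ± 51.5 CPM with 7 of 13 members detected, and its leading members were the sensory organ microRNAs Mir182 (4804 ± 44.0 CPM), Mir183 (1817 ± 42.0 CPM) and Mir96 (895 ± 6.38 CPM). The brain microRNAs Mir124a-1, Mir124a-2 and Mir124a-3 had no count in either library, but they share sequence with each other, so this is not evidence of absence. The liver, gut and endocrine list summed to 621 ± 117 CPM, led by Mir375 (456 ± 98.2 CPM), Mir192 (86.5 ± 14.6 CPM) and Mir194-2 (66.9 ± 1.77 CPM). No test across lists was made.

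The 2 libraries were compared next, to measure the spread within the group. Levels of the 407 genes with at least 10 counts in total followed each other closely (Pearson r = 0.997 and Spearman rho = 0.992 across genes, which are not independent replicates). Of 275 genes with at least 100 counts, 270 lay within 1.5-fold and all 275 within 2-fold of each other. Mir203 was lower in replicate 2 with a log2 ratio of -0.36, Mir206 with -0.45 and Mir10a with -0.34, while Mir375 was higher with 0.44 and Mir214 with 0.21. The biological coefficient of variation estimated with edgeR was 8.80%. A chi-square test of homogeneity gave 21792 on 406 degrees of freedom, 53.7 per degree of freedom. It sets the libraries against counting noise alone, which separate samples at this depth exceed in any case, and it served only to check that the samples were not copies of 1 library.

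By an exact binomial test with Benjamini-Hochberg adjustment, 4 of the 407 genes differed at least 2-fold between the libraries. Mir122, a liver microRNA (6.29 against 13.5 CPM), Mir3057 (1.95 against 5.07 CPM) and Mir5126 (1.52 against 5.55 CPM) were higher in replicate 2, and Mir741 (2.39 against 0.241 CPM) was lower. All rested on few reads: 29 against 56 counts for Mir122, 9 against 21 for Mir3057 and 7 against 23 for Mir5126. Mir741 had 11 against 1 count, the latter below the floor of 3 counts. These 4 genes were named after their values were seen, and Mir3057 missed the threshold with TMM scaling (adjusted p = 0.0524), with DESeq2 size factors (0.0533) and without a count filter (0.0784). None of the 190 genes with a mean of at least 100 CPM passed the 2-fold threshold. At an adjusted p under 0.05 without a fold threshold the test called 145 genes, and 166 had an unadjusted p under 0.05. The test sets reads of 2 libraries against counting noise and compares those libraries, not conditions. With edgeR's exact test at an assumed coefficient of variation of 0.1 or 0.2, 0 genes passed.

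Several lists moved together between the libraries although few single genes differed by much. The Dlk1-Dio3 genes were lower in replicate 2 for 43 of 47 tested members, and for 45 with TMM or DESeq2 scaling, with a median log2 ratio of -0.19, below all of 10000 random lists matched on expression (percentile 0). All 6 tested muscle members were lower (median -0.42, percentile 0.12), among them Mir206, Mir499 (-0.51) and Mir133b (-0.51). All 3 erythroid members were lower (median -0.39, percentile 1.18), with Mir451a at -0.39, Mir144 at -0.43 and Mir486 at -0.01. All 15 members of the miR-17-92 list were higher in replicate 2 (median 0.24, percentile 99.99), and 14 of 15 were with TMM or DESeq2 scaling. The liver, gut and endocrine list had a median of 0.39 (percentile 99.6), with 3 of 4 members higher. Of the 14 lists with at least 3 tested members, these 5 lay outside the middle 95% of random lists. Random lists were drawn gene by gene, whereas neighbours on a strand shared their deviations (intraclass correlation 0.46). The percentiles of lists made of neighbouring genes therefore overstate how unusual their shifts were. The surface epithelium list was lower for 7 of 7 members, but its median of -0.12 (percentile 5.44) lay inside that range. The call of the liver, gut and endocrine list was lost where at least 100 counts were required (percentile 96.98). It was also lost among genes without a shared stretch (percentile 96). The erythroid list was left with too few members to test in both settings.

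**Figure D3:**
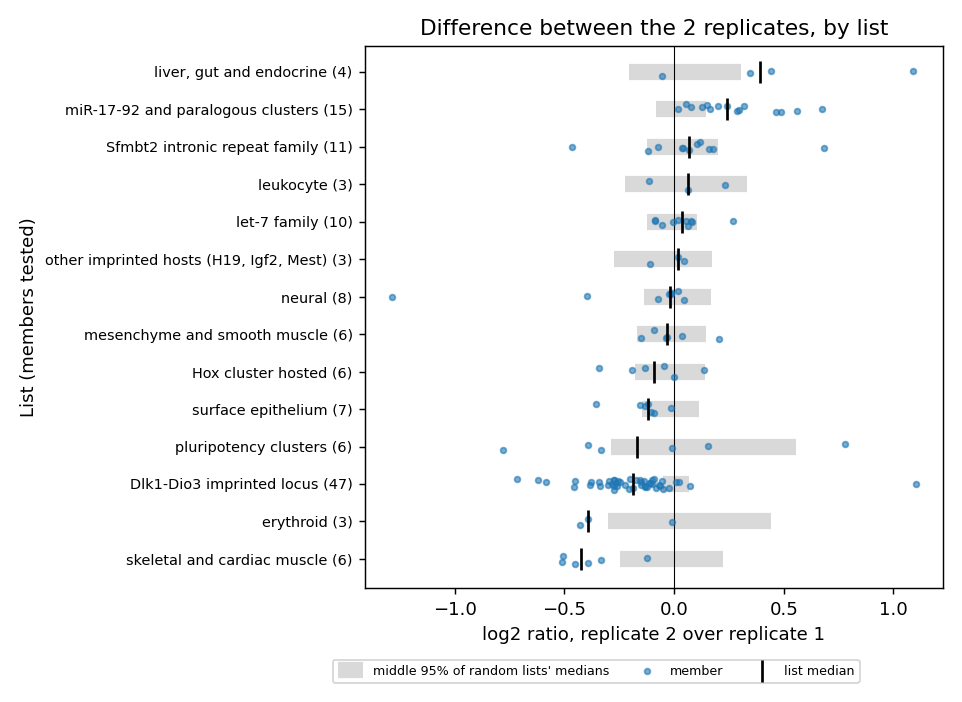
Log2 ratio of replicate 2 over replicate 1 for the tested members (points) of 14 fixed lists, with list medians (bars) and the middle 95% of the medians of 10000 random lists matched on expression (grey). The medians of the muscle, erythroid and Dlk1-Dio3 lists lie left of the grey range, and those of the miR-17-92 list and the liver, gut and endocrine list lie right of it.

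MicroRNA genes that lie close together on a strand are often cut from a shared primary transcript, so the neighbouring genes were compared. Among genes with at least 10 counts in total, 98 fell into 13 clusters of at least 3 genes within 10 kb of the next. Levels inside a cluster differed widely, from 5.37-fold between Mir182 and Mir96 to 10190-fold between Mir411 and Gm27379 in the Dlk1-Dio3 locus, with a median of 78.1-fold. Part of this rests on genes that share a stretch with another gene and may be undercounted, such as Mir24-2, Mir19b-1, Mir3070a and Mir450-2. Among genes without a shared stretch the median was 27.4-fold over 12 clusters, with the same extremes, of which Gm27379 lay near the floor at 1.16 CPM. The deviations between the libraries were shared by neighbours, with an intraclass correlation of the log2 ratios of 0.46 (one-sided permutation p = 1e-05, the smallest that 100000 permutations can give). All 6 genes of the X-linked cluster from Mir363 to Mir106a were higher in replicate 2 (median log2 ratio 0.48), as were all 6 of the Mir17 cluster on chromosome 14 (0.16). All 11 genes from Mir770 to Mir434 were lower (median -0.26), as were 29 of 32 in the cluster from Mir379 to Mir3072 (-0.15; 31 of 32 with either scaling) and all 5 from Mir500 to Mir532 on chromosome X (-0.15). The cluster from Mir322 to Mir450b had a median of -0.01. Genes of a cluster are not independent measurements, and the test compares these 2 libraries alone.

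**Figure D4:**
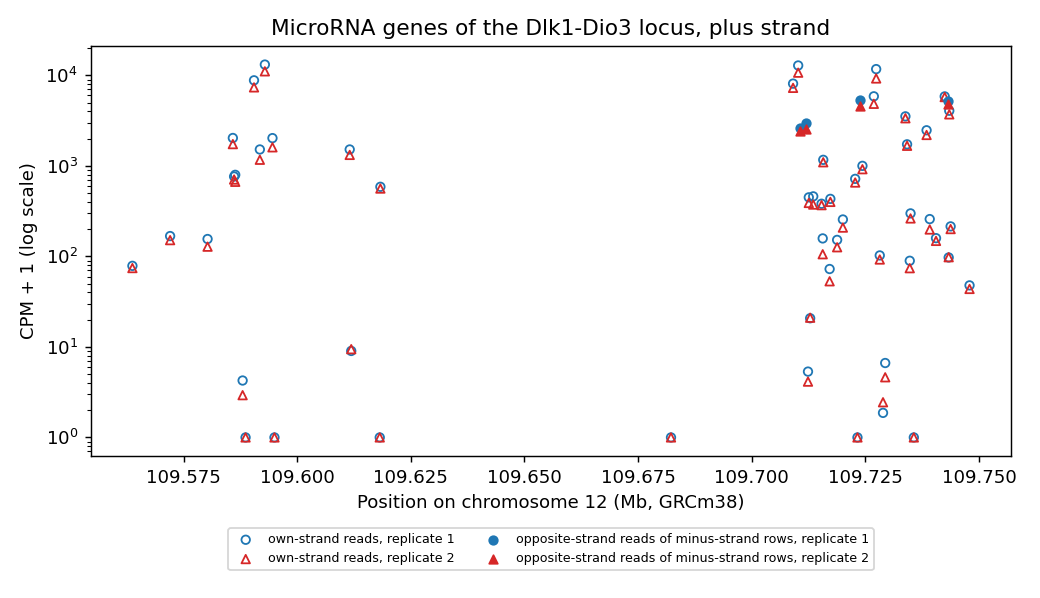
Level of 52 plus-strand microRNA genes of the Dlk1-Dio3 locus as CPM plus 1 on a log axis against their position on chromosome 12 (GRCm38), with replicate 1 in blue and replicate 2 in red. Open symbols are own-strand reads of plus-strand genes and filled symbols are opposite-strand reads of 4 minus-strand genes; most genes lie slightly lower in replicate 2.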

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

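In the paragraphs below, the TMM and DESeq2 settings were planned before the data were examined, though used as a test of the Dlk1-Dio3 pattern only after their results were seen. The GC test was added after the pattern was seen but before its own result, and the remaining tests were chosen after the results were seen.

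Signal appeared in the opposite-strand column, outside the main own-strand measurement, above the limit that a count of 0 allows. It was placed at 11 genes, which held 99.9% of the opposite-strand counts. Opposite-strand reads reached 8045 ± 911 CPM (SD, n = 2) at Gm25301, which lies opposite Mir378a, a microRNA hosted by the metabolic coactivator gene Ppargc1b. They reached 4992 ± 229 CPM at Gm24321 opposite Mir409, 4946 ± 365 CPM at Gm25927 opposite Mirlet7e and 4946 ± 510 CPM at Gm25252 opposite Mir376a. Lower values were 2758 ± 305 CPM at Gm25750 opposite Mir380, 2605 ± 63.2 CPM at Gm24083 opposite Mir191 and 2520 ± 153 CPM at Mir299b opposite Mir299a. Next came 804 ± 25.1 CPM at Mir497b opposite Mir497 and 651 ± 71.3 CPM at Mir142b opposite Mir142, a microRNA of blood cells. The lowest were 79.2 ± 10.1 CPM at Gm24111 opposite Mirlet7f-1 and 67.5 ± 6.20 CPM at Mir3074-1 opposite Mir24-1.

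For these opposite-strand counts, reads assigned to the wrong strand are argued against: the median opposite-strand share of 152 genes with at least 1000 own-strand counts in both libraries was 0%, and the highest was 0.351%. The other explanation, a microRNA gene on the other strand that was not counted on its own strand here, went with the data, since 100% of the 11 genes lay opposite such a gene. A candidate explanation is therefore that these counts belong to Mir378a, Mir409, Mirlet7e and the others. No biological explanation was tested, because the design gives no group to set against it.

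Reads with several alignments made up 32.2% of all reads, a tally outside the gene counts that is above the limit of a count of 0. Among 871 genes that share a stretch of 22 nucleotides with another microRNA gene, 7.12% were detected, against 26.5% of 1023 genes without one. Genes with a shared stretch lay below the other genes of their cluster in 78.6% of the 28 clusters that held both kinds, against 45.6% by chance (one-sided permutation test within clusters, p = 0.00018), and in 85.7% of the 21 clusters whose highest member of either kind had at least 10 CPM. Low levels of genes such as Mir1a-1, Mir133a-1, Mir26a-1 and Mir26a-2 may thus come from reads that were left out of the gene counts. Whether those microRNAs are abundant in the limb stays open, since the reads with several alignments are given as a total only.

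The Dlk1-Dio3 genes were lower in replicate 2. Library scaling is argued against, since the median log2 ratio was -0.23 with TMM and slightly further from 0 with DESeq2 size factors, and so is GC content, with a median of -0.23 after the GC trend was removed. Reads shared between similar genes are argued against by the median of -0.186 over the 45 of 47 members without a shared stretch. That 95.7% of members lay below the median of the genes outside the list restates the pattern. It is no test of a single abundant member, which could not move a median over 47 members. The opposite-strand reads at 4 genes of the locus, none of which entered the list ratio, had a median log2 ratio of -0.17 (-0.23 to -0.09), against 0.06 (-0.23 to 0.26) at the 7 other genes, of which Mir378a (-0.23) and Mir142 (-0.22) were about as low, a difference that was not tested. A difference in embryo stage, tissue mix or dissection could give such a shift, but collection day and replicate are confounded and no biological explanation was tested.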

How the results depend on the processing

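The total with reads of several alignments and the restriction to genes without a shared stretch were chosen after seeing the data. Detection counted 556 genes at a minimum of 1 count in both libraries. The correlation was 0.9985 with a pseudocount of 5, 0.9963 without a filter and 0.9978 at a minimum of 100 counts. The share of the most abundant gene was 6.20% without Mir335 in the total (then the next gene), 24.8% for opposite-strand reads and 4.68% with reads of several alignments. The share of the 10 most abundant genes was 45.9%, 99.7% and 28.8% under these settings and 45.7% for reads on either strand. Genes differing between the replicates numbered 3 with TMM, with DESeq2 size factors and without a filter, each without Mir3057. They numbered 145 at any fold, 7 at 1.5-fold, 0 at a minimum of 100 counts and 0 by edgeR's exact test with an assumed coefficient of variation of either 0.1 or 0.2. Lists outside the random range numbered 3 at a minimum of 100 counts and 3 among genes without a shared stretch, where fewer lists and genes could be tested and the liver, gut and endocrine list came inside. Apart from these by-construction effects the cause was not tested. The coefficient of variation lay between 8.57% and 9.10% in all settings run. Lists at or above 10000 CPM, a level set after the data were examined, numbered 9 of 16 in every setting. The intraclass correlation lay between 0.44 and 0.51. The lists outside the random range kept their direction. Of those inside it, the median log2 ratio changed sign for let-7 (0.04 to -0.003 with TMM and -0.004 with DESeq2), for the other imprinted hosts (0.02 to -0.02 with either scaling or without the GC trend) and for the neural list (-0.02 to 0.002 without shared stretches). Levels of single genes and lists moved by more than the SD of the 2 libraries in 69 cases, all by a change of total or strand. Leaving out a library could not count as a move, since it always shifts the mean by less than the SD of the 2 libraries. Counting the opposite-strand reads at unlisted genes raised the leukocyte list by 104% to 1278 CPM, let-7 to 91179 CPM and Dlk1-Dio3 to 103609 CPM. No paired analysis was possible because there is 1 group. Depth limits the comparison of genes under about 100 counts.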

Other observations

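Several abundant microRNAs of the limb belonged to none of the lists and were chosen here after their values were seen. The X-linked cluster of Mir322, Mir503, Mir351, Mir542 and the Mir450 genes ranged 1715-fold, from Mir450-2 at 31.3 CPM to Mir322 at 53715 CPM. Mir450-2 shares a stretch with another gene, so its count is a lower limit. Among members without a shared stretch the range was 139-fold, from Mir450b at 386 ± 42.5 CPM. The family of Mir99a also included Mir100 at 11547 ± 264 CPM (SD, n = 2) and Mir99b at 16252 ± 1314 CPM. Mir125a, the neighbour of Mir99b, reached 4044 ± 324 CPM. Mir181c and Mir181d in an intron of Nanos3 reached 6919 ± 346 CPM and 5299 ± 466 CPM, and Mir21a, a microRNA often raised in injury, which overlaps Vmp1, reached 7520 ± 229 CPM. Neighbours cut from a shared transcript differed here too, with Mir23b at 44668 CPM against Mir27b at 5161 ± 326 CPM, and Mir23a at 20383 CPM against Mir27a at 510 ± 5.39 CPM.

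The tests below were chosen after related values had been seen. The higher level of the X-linked cluster from Mir363 to Mir106a in replicate 2 raised the hypothesis that X-linked microRNA genes may be higher in that library. A rise of all X-linked genes is argued against: 83.3% of the 12 genes in the other X-linked clusters were lower in replicate 2, among them all 5 from Mir500 to Mir532 (median log2 ratio -0.15). The 12 genes come only from that cluster and the cluster from Mir450b to Mir322, and neighbours are not independent measurements. Their share therefore says little about X-linked loci on balance. Gene by gene, the 40 other X-linked genes had a median of 0.10 against 0.03 for 361 autosomal genes (two-sided permutation p = 0.104), a test that treats neighbours as independent. With neighbours within 10 kb taken as 1 locus, 20 of 25 X-linked loci lay above 0. The 25 had a median of 0.29 against 0.05 for 266 autosomal loci. The difference was 0.232 (two-sided permutation p = 6e-05 within 5 bins of expression, and permutation p = 0.00043 without bins). The 14 X-linked loci under 100 CPM had a median of 0.50 and the 11 above it one of 0.06. Whether X-linked loci were higher on balance thus depends on how neighbours are weighted and on the level of the loci, and stays open.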
